A study of Mus musculus with 9 samples.

How the data were processed

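RNA was measured in purified mouse CD8 T cells that carried a transgenic T cell receptor, on 9 single-colour Affymetrix arrays of the custom GLYCOv4 design. This array carries probe sets for glycosylation enzymes, lectins, proteoglycans, cytokines, chemokines and their receptors. The samples formed 3 groups of 3 arrays, as the labels give them. Naive cells were the control, deletion cells had met their antigen in vivo as a weak signal, and anergy cells had met it in vivo as a strong signal. All samples were labelled as female. The labels number the samples of a group as replicates and do not say that each came from a separate animal, so the p-values measure only the spread between these samples, which may be technical.

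Total RNA was extracted with Trizol and biotin-labelled cRNA was made from 0.5 micrograms of it, per the labels' protocols. The deposited values are on the log2 scale, with 1 value per probe set and array, and RMA is the only step named in the submitters' processing notes. Its version, the annotation of the array and any filter were not given in the sources used here. The log2 scale was read from the name of that method and from the range of the values, 1.67 to 13.86. Probe sets had not been centred, and single-colour values carry no direction to settle. The array medians were 4.47, 4.44 and 4.49 in naive replicates 1 to 3, 4.49, 4.44 and 4.50 in deletion replicates 1 to 3, and 4.485, 4.475 and 4.58 in anergy replicates 1 to 3. No background or detection column was used here, so no probe set was called detected or absent, and a fold change of a gene near the lowest values understates the real one. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.087 on the log2 scale.

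The table held 1246 probe sets, and none was a control. Probe sets were named by matching their RefSeq accession, without its version, to a RefSeq gene table of the GRCm38.p6 assembly, which was used for names only. This named 963 probe sets (77.3%) as 909 genes, of which 48 had several probe sets. The other 283 stayed unnamed, 261 of them because they carry UCSC identifiers that the table does not hold. Probe sets with the suffixes s (237), x (38) and a (91) can bind more than 1 transcript. A gene with several probe sets was represented by the one with the highest mean over the 9 arrays, and no gene had probe sets past the threshold in opposite directions.

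Values were used as deposited, with no further normalization and no filter. The 3 contrasts between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 9 arrays, with no block, which left 6 residual degrees of freedom and 3.65 prior degrees of freedom. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 1246 probe sets of a comparison, with a threshold of 0.05. Changes are given with their standard error (SE) and group means with their standard deviation (SD). Arrays of deletion and anergy with the same replicate number deviated together from their group means, at r = 0.195, 0.270 and 0.280, so for this comparison the blocked value is given beside a result where the block changes its call. This pairing comes from the data and not from the labels, and it was adopted for this comparison after the calls of the blocked fit had been seen. Gene lists were tested with camera at a preset correlation of 0.01, which sets a list against the other genes of this targeted array and not against the transcriptome. From textbook knowledge 36 lists were fixed before the data were examined. Those with at least 5 measured genes were tested, and so was the pooled list of glycan-processing genes, in all 31 lists and 93 tests in 1 family. No list call held with an estimated correlation.

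The genes to be named were set by a rule, also before the data were examined. For each comparison it took the 12 largest rises and the 12 largest falls past the threshold among probe sets with a symbol and with replicates that did not overlap, and up to 4 members of each list past the threshold with the smallest adjusted p. It also took 12 preset genes whatever their result: St3gal1, St6gal1, Gcnt1, Mgat5, Fut7, Ogt, Lgals1, Lgals3, C1galt1, St3gal4, St3gal6 and Cmah. Other genes named in the text were chosen after their values were seen, and they are given as members of a list or said to be chosen. Results of some single genes that the rule named are not reported here.

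The fit was tested on simulated data in which 200 of the 1246 probe sets changed in each of 20 draws. For deletion against anergy it recovered 93.8% of changes of 0.5 on the log2 scale and 99.8% of changes of 1, and 4.29% of its calls were false. A shift of 0.5 given to the 24 genes of a list was called by camera in 10 of 10 draws. The simulated noise was independent between probe sets and equally wide on all arrays. In the data anergy replicate 3 had a wider spread, and the estimated correlation within that list was 0.20. For deletion against anergy 42 probe sets passed in the data, fewer than the 200 changed in each draw. With fewer changes the adjustment sets a stricter limit. These shares may therefore overstate what the tests recover here, and a gene or list that did not pass was not shown to be unchanged. The alternatives tried were quantile normalization, median centring, leaving out the dimmest 33.3% of probe sets, trend and robust moderation, no moderation, only the 2 groups compared, array weights (statmod 1.5.0), a replicate block, a 2-fold minimum, the mean over probe sets, fry and an estimated correlation for lists, and leaving out each array in turn. Their effect is given in the closing section, and that of the estimated correlation beside each list call. Fry, which does not set a list against the other genes, called further lists that camera did not. Among them were O-GalNAc initiation in deletion against naive (down, fry adjusted p = 0.000112) and sialyltransferases in deletion against anergy (up, fry adjusted p = 0.00528). It did not call the lysosomal list in deletion against anergy (fry adjusted p = 0.0780). Figures were drawn with matplotlib 3.10.9.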

Results

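The data were 9 arrays of transgenic CD8 T cells from the B10D2 mouse strain: 3 of naive cells, 3 of cells given a weak antigen signal in vivo (deletion conditions) and 3 of cells given a strong antigen signal in vivo (anergy conditions). Both treatments lead to tolerance, the first by loss of the cells and the second by their unresponsiveness, and the design asked which glycosylation transcripts differ between these cells. Each array gave log2 expression values of 1246 probe sets. The first principal component held 82.9% of the variance and set the naive arrays (-16.37 to -15.23) apart from the deletion arrays (5.87 to 6.60) and the anergy arrays (9.22 to 9.98). The second held 7.18% and set deletion (-5.16 to -2.57) apart from anergy (1.41 to 6.82). Replicates of a group correlated at 0.995 to 0.998 across probe sets. Anergy replicate 3 stood apart from its group, with a residual SD of 0.166 on the log2 scale against 0.094 to 0.128 in the other 8 arrays.

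The comparison named as the study's purpose was deletion against anergy. St6gal1, which adds alpha-2,6-linked sialic acid to N-glycans, was 2.80-fold higher in deletion cells (95% limits 2.23 to 3.50; n = 3 arrays per group; adjusted p = 0.000368). St8sia1, which makes the ganglioside GD3, was 2.46-fold higher (2.03 to 2.97; adjusted p = 0.000368), and Galnt10, one of the enzymes that start O-GalNAc glycans, was 2.00-fold higher (1.63 to 2.47; 6.24 ± 0.08 against 5.23 ± 0.23, SD; adjusted p = 0.00275). Among genes with no part in glycan synthesis, Igf1r, the receptor of insulin-like growth factor 1, was 3.07-fold higher in deletion cells (2.07 to 4.56, adjusted p = 0.00637). Its log2 values in anergy replicates 1 to 3 were 4.97, 4.75 and 3.80, the lowest of them on the array that stood apart. The call held in 16 of 17 settings and was lost when limma was fitted to only the 2 groups (adjusted p = 0.0602). Klrc1, the inhibitory lectin receptor NKG2A, was 3.65-fold lower in deletion cells than in anergy cells (2.74 to 4.85; 6.75 ± 0.36 against 8.61 ± 0.07; adjusted p = 0.000368), and Il1rl1, the interleukin-33 receptor, was 3.60-fold lower (2.83 to 4.57; adjusted p = 0.000252).

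In all, 26 probe sets were higher and 16 lower in deletion than in anergy, 42 of 1246 (3.37%), and 5 and 6 of them differed by at least 2-fold. The named ones were 23 genes higher and 13 lower. All 42 had replicates that did not overlap between the groups, as chance gives for 10% of probe sets and as was seen for 16.6% of all 1246. The split of 26 against 16 became 32 against 38 after quantile normalization and 13 against 13 after median centring, and none of the 42 changed sign under either. The higher count fell to 8 without deletion replicate 2, 14 without deletion replicate 3, 15 without anergy replicate 2 and 17 without anergy replicate 3, the array that stood apart.

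Of 244 measured glycan-processing genes, 11 were higher in deletion, 2 were lower and 231 did not pass, and adjusted over the list alone the counts were 20 and 6. These counts became 12 and 15 after quantile normalization and 5 and 0 after median centring, and 6 and 5 without anergy replicate 3, and the list as a whole was not called (adjusted p = 0.240). Sialyltransferases gave 3 of the 11: St6gal1, St8sia1 and St3gal4, the last of which sialylates selectin ligands and differed by 0.44 ± 0.09 on the log2 scale (SE; adjusted p = 0.0315). The other 16 measured sialyltransferases did not pass, among them St3gal1 with 0.48 ± 0.11 (adjusted p = 0.0540) and St3gal6 with 0.01 ± 0.09; adjusted over the list alone 5 were higher and 0 lower, and camera gave an adjusted p of 0.329. The call of St3gal4 held in 8 of 17 settings, those of St6gal1 and St8sia1 in all 17.

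Transcripts of 3 chondroitin sulfotransferases passed, not all in the same direction. Chst3, a chondroitin 6-O-sulfotransferase, was 0.91 ± 0.18 higher in deletion (SE; adjusted p = 0.0231), while the 4-O-sulfotransferases Chst12 and Chst11 were lower, at -0.57 ± 0.13 (adjusted p = 0.0458) and -0.32 ± 0.07 (adjusted p = 0.0358). Slc35b3, which carries the sulfate donor into the Golgi, was higher by 0.68 ± 0.13, and Xylt2, which starts glycosaminoglycan chains, by 0.51 ± 0.10. Together these 5 were the members of the heparan and chondroitin sulfate list that passed, 3 higher and 2 lower of 43 measured (adjusted over the list alone 4 and 2; camera adjusted p = 0.304). After median centring only 1 of the 43 was higher and 0 were lower, and of 17 settings Chst3 passed in 11, Slc35b3 in 12, Xylt2 in 10 and Chst11 and Chst12 in 8 each. Agrn, the core protein of agrin and a gene of the proteoglycan list, was higher by 0.54 ± 0.12 (adjusted p = 0.0335), the only 1 of that list's 22 measured genes to pass. Its call held in 9 of 17 settings and was lost after median centring, without anergy replicate 3 and with a replicate block (adjusted p = 0.0535).

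Of 24 measured genes of lysosomal glycan degradation, 3 were higher in deletion, 0 were lower and 21 did not pass, and adjusted over the list alone 9 were higher and 1 lower. They included Gm2a, the cofactor that presents ganglioside GM2 for cleavage (0.40 ± 0.08), and Arsa, which removes sulfate from sulfatide (0.34 ± 0.07). Camera called the list higher (adjusted p = 0.0485), and adjusted p = 0.685 with an estimated correlation. This call was lost under both scalings, with a replicate block (adjusted p = 0.0615) and without any 1 of 7 arrays, and after quantile normalization 2 members were higher and 2 lower. Pigp, of the first step of GPI anchor synthesis, was higher by 0.42 ± 0.09, with 1 higher and 0 lower of 7 in its list, and 0 higher after median centring or without anergy replicate 3 (9 of 17 settings held). Of the nucleotide sugar list, Slc35b3 alone passed among 40 genes, although 1 was higher and 7 were lower after quantile normalization. The preset genes Gcnt1 (0.02 ± 0.15), Mgat5 (-0.09 ± 0.09), C1galt1 (0.06 ± 0.10), Ogt (0.26 ± 0.18), Cmah (0.26 ± 0.11), Lgals1 (-0.27 ± 0.14), Lgals3 (-0.50 ± 0.17) and Fut7 (0.63 ± 0.15, adjusted p = 0.0523) did not pass. Fut7 passed with a replicate block (adjusted p = 0.00422), after quantile normalization (0.0463) and with array weights (0.0401), and not after median centring (0.0855) or without anergy replicate 3 (0.152).

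Outside glycan synthesis, 4 of 13 measured T cell activation, inhibition and effector genes were lower in deletion and 0 were higher (adjusted over the list alone 6 and 1). These were Il2ra, the alpha chain of the interleukin-2 receptor (-1.05 ± 0.11), Prdm1, the transcription factor Blimp-1 (-0.80 ± 0.12), Havcr2, the inhibitory receptor Tim-3 (-0.76 ± 0.12), and Il21 (-0.56 ± 0.08, at means of 2.11 and 2.67, close to the lowest values of the arrays). Ifng, Ccl3, Ccl4 and Xcl1 of the same list went the other way, higher in deletion by 0.34, 0.22, 0.86 and 0.47, and did not pass. The list was not called by camera (adjusted p = 0.240, direction down, with a median of 0.22 and a mean of -0.07). Glycosphingolipid genes (median -0.02, mean 0.04, direction down), galectins (0.02, -0.01, down) and macrophage and dendritic cell markers (-0.02, 0.02, down) also had values of unlike sign, and none was called. Of 63 interleukins and receptors, 4 were lower (Il1rl1, Il2ra, Il12rb2 at -0.69 ± 0.07, and Il21) and 1 was higher (Il27ra at 0.47 ± 0.07). A different probe set of Il1rl1 gave -0.11 and did not pass. Of 47 chemokines and receptors, Ccr6 (-1.07 ± 0.11) and Cxcr4 (-0.74 ± 0.14, past the threshold in 11 of 17 settings) were lower and 0 were higher, with 4 lower after quantile normalization and 1 after median centring. Klrc3 (-0.56 ± 0.10) was lower beside Klrc1 among 17 lectin receptors of the natural killer type, of which 1 was lower without anergy replicate 3. The adhesion list had 2 of 13 higher, Pecam1 (0.72 ± 0.09) and the integrin chain Itgae (0.44 ± 0.09), and 0 lower, and 1 higher without anergy replicate 3.

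Further genes higher in deletion were Igfbp7, which binds insulin-like growth factors (1.06 ± 0.07, adjusted p = 7.3e-05), Cd83, a surface marker of activation (1.00 ± 0.22), Cd2, an adhesion receptor of T cells (0.61 ± 0.14), Lipa, the lysosomal acid lipase (0.60 ± 0.12), and Csf2ra (0.55 ± 0.12). Of 17 settings Cd83 passed in 10, Cd2 in 8, Lipa in 13 and Csf2ra in 9. Aldoa, a glycolytic enzyme, was lower, at -0.48 ± 0.06 and -0.44 in its 2 probe sets, a call lost after quantile normalization (adjusted p = 0.261, the highest of its 17 settings). Of 34 named genes that passed, 14 did so in every setting run for single genes: St6gal1, St8sia1, Galnt10, Igfbp7, Pecam1, Il27ra, Klrc1, Il1rl1, Ccr6, Il2ra, Prdm1, Havcr2, Il12rb2 and Il21. The fit with no moderation and the 2-fold limit were run for the counts of probe sets and not for single genes. With no moderation 5 probe sets were higher, fewer than the higher genes named here, and 9 were lower. For Il12rb2 and Il21 only 16 settings were run, since both lay in the dimmest 33.3% of probe sets that 1 setting left out. The means of Il12rb2 were 3.15 in deletion and 3.84 in anergy.

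**Figure D1:**
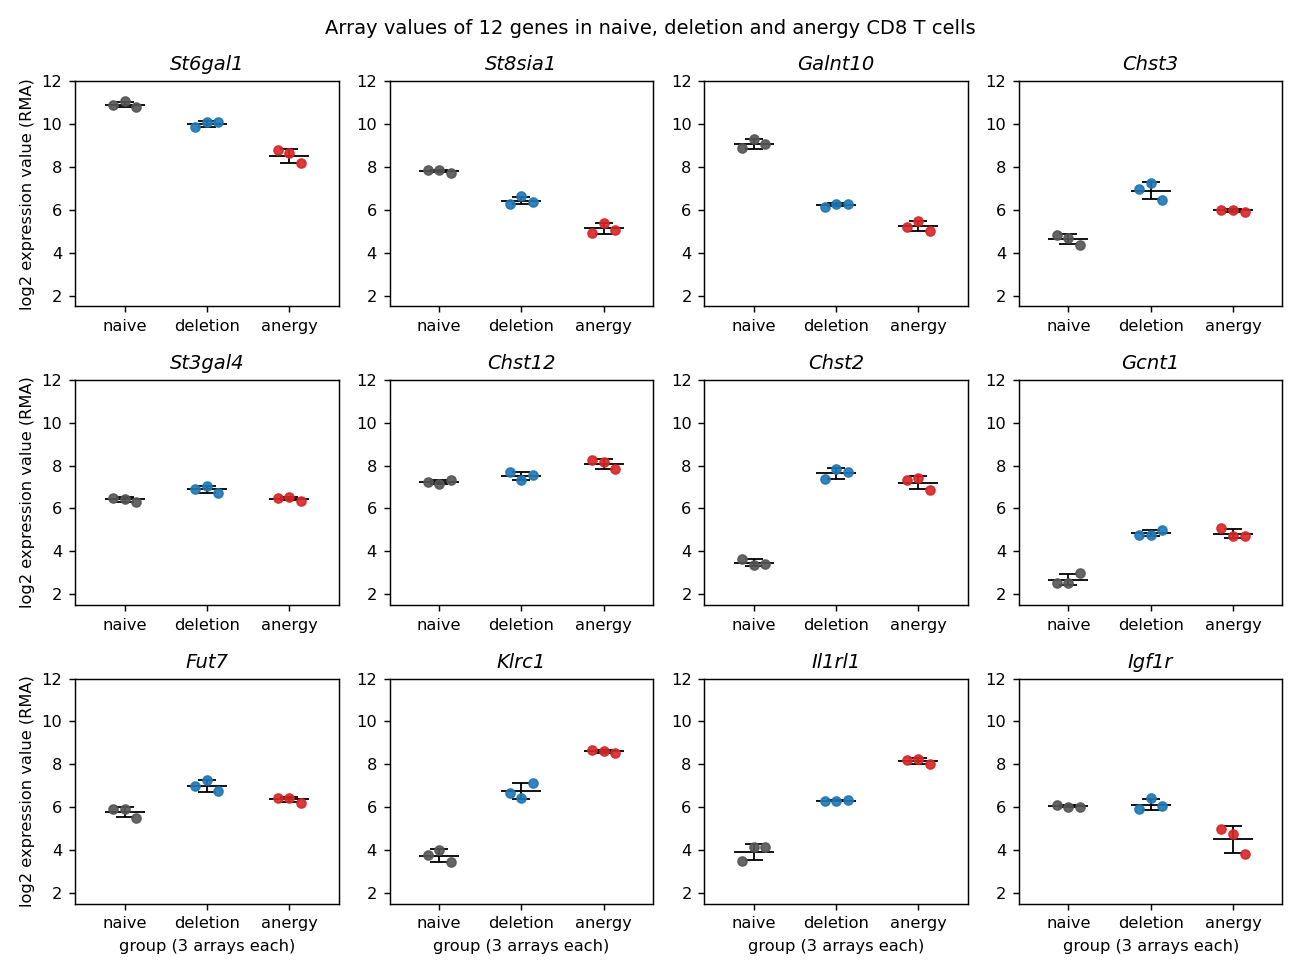
Log2 expression values (vertical axis) of 12 genes in naive, deletion and anergy cells, with 1 point per array, bars at the group means and whiskers of 1 SD (n = 3). Galnt10 fell from a mean of 9.08 in naive to 6.24 in deletion and 5.23 in anergy, while Klrc1 rose from 3.74 to 6.75 and 8.61.

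Markers of other cells were mostly level between deletion and anergy. None of 7 B cell, 23 macrophage and dendritic cell, 4 natural killer cell or 4 erythroid and granulocyte markers passed in limma. For the endothelial, stromal and platelet list 1 of 12 was higher, Pecam1, and for the CD4 and regulatory T cell list 1 of 4 was lower, Il2ra, and T cells express both genes too. Cd2 was the only measured gene of the T cell identity list, and 0 of 25 apoptosis genes of the list fixed beforehand were measured.

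Deletion cells were then compared with naive cells, the control population. Genes of effector T cells were among the largest rises: Xcl1, a chemokine of activated CD8 T cells, was 55.3-fold higher in deletion (95% limits 40.1 to 76.3; 11.19 ± 0.48 against 5.40 ± 0.25, SD, n = 3 arrays per group; adjusted p = 2.2e-08), Ifng 20.8-fold (12.5 to 34.5), Ccl3 19.3-fold (13.7 to 27.1) and Ccl4 17.6-fold (12.2 to 25.5). Among glycosylation enzymes the largest rise was that of Chst2, which sulfates GlcNAc on selectin ligands, at 17.9-fold (13.8 to 23.2; adjusted p = 5.4e-08). With 1 probe set per gene, the largest falls were those of Ccr9, a homing receptor for the gut, at 30.2-fold (24.5 to 37.2), and Itgae, the integrin chain CD103, at 25.3-fold (22.2 to 28.8). Galnt10 fell 7.18-fold (5.83 to 8.83; adjusted p = 1.9e-07). In all, 106 probe sets rose and 131 fell, 32 and 27 of them by at least 2-fold.

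Of the 244 glycan-processing genes, 25 rose, 40 fell and 179 did not pass (29 and 42 adjusted over the list alone). The enzymes that start O-GalNAc glycans gave 5 falls and 0 rises among 19 measured: Galnt10 (-2.84 ± 0.13, SE), Galnt6 (-1.47 ± 0.07), Galnt11 (-0.83 ± 0.12), Galnt2 (-0.47 ± 0.10) and Galnt12. In the extension of these glycans 2 of 13 genes rose and 0 fell. They were Gcnt1, the core 2 branching enzyme (2.17 ± 0.15; the other probe set of the gene gave 0.19 and did not pass), and B4galt5 (0.96 ± 0.09). Of 12 genes that make or carry selectin ligands, 5 rose and 2 fell: Chst2 (4.16 ± 0.17), Gcnt1, the carrier Cd44 (1.85 ± 0.17), the fucosyltransferase Fut7 (1.20 ± 0.15) and St3gal4 (0.48 ± 0.09) rose, and B4galt1 (-0.62 ± 0.10) and Tpst2 (-0.50) fell. None of these 3 lists was called by camera (adjusted p = 0.240, 0.448 and 0.240).

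Of 19 sialyltransferases, St3gal4 rose, and St8sia1 (-1.37 ± 0.12), St6gal1 (-0.90 ± 0.15) and St3gal3 (-0.60 ± 0.07) fell. In sialic acid metabolism Nans, a synthase of sialic acid, rose (0.67 ± 0.12), and Cmah, which makes N-glycolylneuraminic acid (-0.72 ± 0.11), the sialidase Neu1 (-0.72 ± 0.09) and Ctsa fell, 1 and 3 of 12. Among 43 heparan and chondroitin sulfate genes 3 rose, with Chst3 at 2.26 ± 0.18, and 7 fell, with Hs6st1 at -1.28 ± 0.09, Xylt2 at -0.78 ± 0.10 and Chst15 at -0.75 ± 0.12. Of 33 sulfotransferases 3 rose and 4 fell, among them Chst10 (-1.39 ± 0.07). In N-glycan branching 4 of 21 rose, with B3gnt2 at 0.73 ± 0.10, and 3 fell, with Man2a2 at -1.06 ± 0.23. The precursor list had 3 rises and 2 falls among 16, with Dpagt1 at 0.36 ± 0.09 and Alg1 at -0.77 ± 0.09. After median centring the precursor list had 0 rises and 2 falls, with Dpagt1 no longer past the threshold (adjusted p = 0.0571), and the branching list had 2 rises. The precursor counts were 5 and 2 after quantile normalization and 6 and 4 without anergy replicate 3. In fucosylation 2 of 14 rose, Fut7 and Gmds (0.85 ± 0.14), and 2 fell. The nucleotide sugar list had 8 rises and 3 falls among 40, with Uap1l1 (0.97 ± 0.12), Pmm1 (0.78 ± 0.13) and Gnpda1 (0.67 ± 0.07), and 1 fall instead of 3 after median centring. For glycosphingolipids 2 of 19 rose, with B3gnt5 at 0.90 ± 0.17, and 1 fell. For GPI anchors 1 of 7 rose and 2 fell, with Piga at -0.98 ± 0.15 and with 0 rises after median centring. For lysosomal degradation 2 of 24 rose and 8 fell, with Gaa at -0.90 ± 0.11 and Galc at -0.78 ± 0.10 (4 rises after quantile normalization and 1 after median centring). Median, mean and camera direction differed in sign for fucosylation (-0.05, 0.07, up), sulfotransferases (-0.06, 0.04, down), N-glycan branching (-0.01, 0.03, up), N-glycan precursors (-0.01, 0.01, up), glycosphingolipids (-0.01, 0.03, up) and sialic acid metabolism (0.01, -0.04, up), none of them called.

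Camera called 2 lists in deletion against naive. T cell activation, inhibition and effector genes were higher, with 6 of 13 up and 0 down (adjusted p = 0.00127), and adjusted p = 0.685 with an estimated correlation. The 6 were Xcl1, Ifng, Ccl3, Ccl4, Il2rb (1.78 ± 0.09) and Il2. Naive and memory T cell genes were lower, with 0 of 6 up and 4 down: Ccr9, Igfbp4, the interleukin-7 receptor Il7r (-2.25 ± 0.20) and the lymph node homing receptor Ccr7 (-0.99 ± 0.16), at adjusted p = 0.000798, and adjusted p = 0.228 with an estimated correlation. Igfbp4 fell by 2.95 on the log2 scale in the probe set with the highest mean and by 4.36 and 5.14 in its other probe sets. Both galectins Lgals1 (2.86 ± 0.14) and Lgals3 (3.15 ± 0.17), which bind galactose-containing glycans, rose, with 3 of 10 in their list up and 1 down. The proteoglycan list had 2 of 22 up, with Vcan at 0.98 ± 0.09, and 4 down, with Agrn at -1.32 ± 0.12 and Tgfbr3 at -3.29 ± 0.11, and 1 up under either scaling. Cks1b and Cks2, small subunits of cell cycle kinases, rose by 3.14 ± 0.17 and 3.18 ± 0.24, and Cd83, Igfbp7 and Klrc1 rose by 2.82 ± 0.22, 2.82 ± 0.07 and 3.01 ± 0.18.

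Some markers of other cells passed against naive. Of 7 B cell markers Cd22 (1.17 ± 0.16) and Cxcr5 (0.64 ± 0.15) rose and Cd72 (-1.56 ± 0.17) fell in deletion. Ly75 alone fell among 23 macrophage and dendritic cell markers, Siglecf alone rose among 4 erythroid and granulocyte markers (0.33 ± 0.09). Ccr4 alone fell among 4 CD4 and regulatory T cell markers (-0.24), Pecam1 alone rose among 12 endothelial, stromal and platelet markers (0.43), and 0 of 4 natural killer cell markers passed. Siglecf and Ccr4 did not pass after median centring.

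Anergy cells were compared with the same naive cells. Xcl1 was 39.9-fold higher in anergy (28.9 to 55.0; 10.72 ± 0.07 against 5.40 ± 0.25, SD, n = 3 arrays per group; adjusted p = 3.8e-08), Klrc1 29.4-fold (22.1 to 39.1), Il1rl1 18.7-fold (14.7 to 23.7), Ccl3 16.6-fold, Ifng 16.4-fold and Chst2 13.2-fold (10.2 to 17.1). Ccr9 fell 41.5-fold (33.8 to 51.1), Itgae 34.4-fold (30.1 to 39.2), Galnt10 14.4-fold (11.7 to 17.7), St8sia1 6.36-fold (5.26 to 7.71; adjusted p = 1.1e-07) and St6gal1 5.22-fold (4.16 to 6.54; adjusted p = 9.3e-07). In all, 134 probe sets rose and 200 fell, 38 and 42 of them by at least 2-fold. Without anergy replicate 3, the array that stood apart, 150 rose and 180 fell.

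Of the 244 glycan-processing genes 34 rose, 57 fell and 153 did not pass (35 and 59 adjusted over the list alone), and 51 rose and 55 fell after quantile normalization. Sialyltransferases gave 2 rises and 5 falls among 19: St3gal5, which makes the ganglioside GM3 (0.52 ± 0.10, SE), and St6galnac6 rose, and St8sia1, St6gal1, St3gal1 (-0.77 ± 0.11), St3gal3 (-0.62 ± 0.07) and St8sia6 (-0.49) fell. The O-GalNAc initiating enzymes again gave 5 falls and 0 rises among 19, with Galnt10 at -3.85 ± 0.13, Galnt6 at -1.73 ± 0.07 and Galnt11 at -1.32 ± 0.12. In their extension Gcnt1 (2.15 ± 0.15) and B4galt5 (1.30 ± 0.09) rose and St3gal1 fell, 2 and 1 of 13. Of the selectin ligand genes 4 of 12 rose, Chst2, Gcnt1, Cd44 (1.97 ± 0.17) and Fut7 (0.58 ± 0.15), and 2 fell, Tpst2 (-0.75 ± 0.07) and B4galt1 (-0.74 ± 0.10). Among 43 heparan and chondroitin sulfate genes 4 rose, Chst3 (1.35), Chst12 (0.85), Chsy1 (0.77) and Chst11 (0.69 ± 0.07), and 12 fell, with Hs6st1 at -1.58 ± 0.09 and Xylt2 at -1.29 ± 0.10.

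Camera called 4 lists in anergy against naive. T cell activation, inhibition and effector genes were higher, with 10 of 13 up and 1 down, Ccl5, which did not pass after quantile normalization or without anergy replicate 3 (list adjusted p = 2.6e-05), and adjusted p = 0.685 with an estimated correlation. They included Il2rb (2.09 ± 0.09), Il2ra (1.16 ± 0.11), Havcr2 (0.86), Prdm1 (0.72) and Il10 (0.35). Naive and memory T cell genes were lower, with 5 of 6 down and 0 up (adjusted p = 0.000423), and adjusted p = 0.228 with an estimated correlation; Ccr9, Igfbp4 (-3.12 ± 0.13), Il7r (-2.39 ± 0.20) and Ccr7 (-1.40 ± 0.16) were among the falls. Lysosomal glycan degradation was lower, with 12 of 24 down and 3 up (adjusted p = 0.0485), and adjusted p = 0.685 with an estimated correlation. Neu1 (-1.02 ± 0.09), Idua (-0.85), Arsa (-0.77 ± 0.07) and Hexa (-0.66 ± 0.08) fell, and Arsb (1.09 ± 0.11), Hpse (0.60) and Gusb (0.32) rose. The list of O-mannose, O-fucose, O-glucose and O-GlcNAc enzymes was lower, with 6 of 13 down and 0 up (adjusted p = 0.0440), and adjusted p = 0.685 with an estimated correlation. The Notch-modifying enzymes Mfng (-0.67 ± 0.10) and Lfng (-0.62), Pomgnt1 (-0.53 ± 0.07), Pofut2 (-0.45 ± 0.08) and Pomt2 (-0.27) were among the falls, and Ogt stood at -0.49 ± 0.18 (adjusted p = 0.0865). The lysosomal and O-mannose calls were lost under both scalings and without anergy replicate 3, although 12 and 6 genes of these lists were lower after either scaling too.

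In the remaining lists the nucleotide sugar genes had 11 of 40 up and 5 down, with Pmm1 at 1.19 ± 0.13, Gmds at 1.17 ± 0.14 and Gnpda1 at 0.94 ± 0.07 up, and 7 up instead of 11 after median centring. The N-glycan precursor list had 6 of 16 up and 4 down, with Alg1 at -1.01 ± 0.09 (2 down after quantile normalization), the branching list 4 of 21 up and 3 down, with Man2a2 at -1.67 ± 0.23 (7 up after quantile normalization), and fucosylation 3 of 14 up and 3 down, with Fut8, which adds core fucose, at 0.42 ± 0.10. Galectins gave 3 of 10 up, with Lgals3 at 3.65 ± 0.17 and Lgals1 at 3.13 ± 0.14, and 3 down, with Lgals8 at -0.66 ± 0.10. Of 17 lectin receptors of the natural killer type 4 rose, with Klrk1, the activating receptor NKG2D, at 0.79 ± 0.14, and 2 fell, with Klrd1, the partner chain of NKG2A, at -0.92 ± 0.10 (1 fall after quantile normalization). Median, mean and camera direction differed in sign for fucosylation (-0.08, 0.03, down) and B cell markers (0.10, -0.02, up), among others, and neither was called. In sialic acid metabolism, also of unlike sign (0.02, -0.14, down) and not called, 1 of 12 rose and 3 fell, with Cmah at -0.98 ± 0.11. Among other-cell markers Cd22 (0.98 ± 0.16) rose and Cd72 (-1.64 ± 0.17) fell. Cx3cr1 (0.44 ± 0.07) rose and Ly75 (-0.65 ± 0.10) fell. Siglecf (0.39) rose, Il2ra rose and Ccr4 (-0.26) fell, Pecam1 (-0.30, past the threshold in 7 of 17 settings) fell, and 0 of 4 natural killer cell markers passed.

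**Figure D2:**
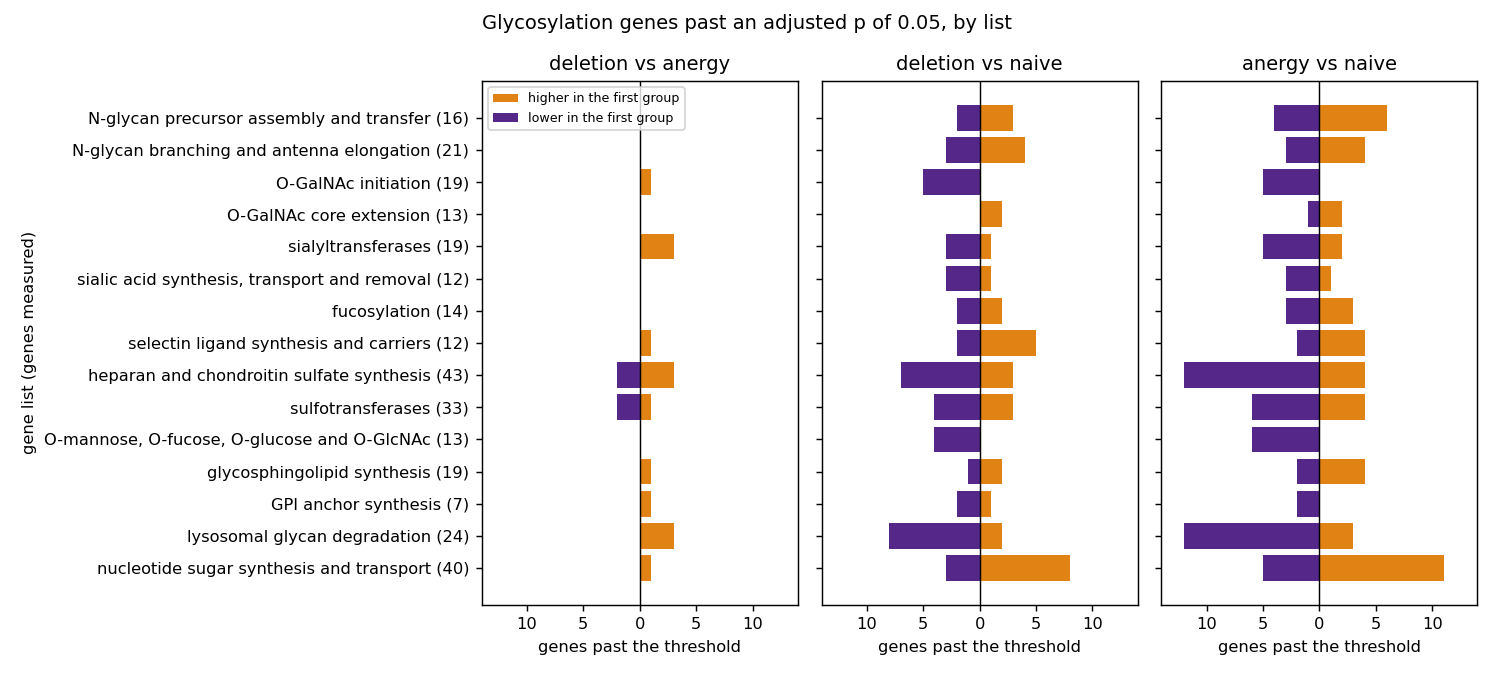
Number of genes past an adjusted p of 0.05 (horizontal axis) in 15 lists of glycosylation genes for the 3 comparisons, with genes higher in the first-named group to the right of 0 and lower ones to the left; measured genes per list stand in brackets and some genes belong to several lists. Against naive, the lysosomal list had 8 lower genes in deletion and 12 in anergy, and the O-GalNAc initiation list had 5 lower genes in both.

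The changes of both stimulated groups against naive were set side by side. Across the 1246 probe sets, which are not independent replicates, the log2 changes correlated at r = 0.950 with a covariance of 0.442, whereas unchanged groups set against the same 3 naive arrays gave r = 0.500 and a covariance of 0.00553 (means of 100 simulated draws). In both groups 85 probe sets rose and 125 fell, where independent lists of these sizes would share 11.4 and 21.0. In the simulated draws of unchanged groups at most 1 probe set passed in both comparisons, so the shared naive arrays alone did not give counts of this size. A part of the excess may still come from these arrays, which were too few to divide. Il12rb2 and Pecam1 alone passed in both comparisons in opposite directions: Il12rb2 fell in deletion (-0.42) and rose in anergy (0.27), and Pecam1 rose in deletion (0.43) and fell in anergy (-0.30), although the fall of Pecam1 did not pass under either scaling. Of the 210 probe sets that changed the same way, 155 (73.8%) lay farther from naive in anergy than in deletion. Of the 42 probe sets that differed between deletion and anergy, 27 lay in deletion between the naive and the anergy mean, such as St6gal1, St8sia1, Galnt10, Klrc1 and Il1rl1. Another 6 lay beyond the anergy mean on the same side of naive, such as Chst3, Cd83 and Igfbp7, and 9 lay on the other side of naive.

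**Figure D3:**
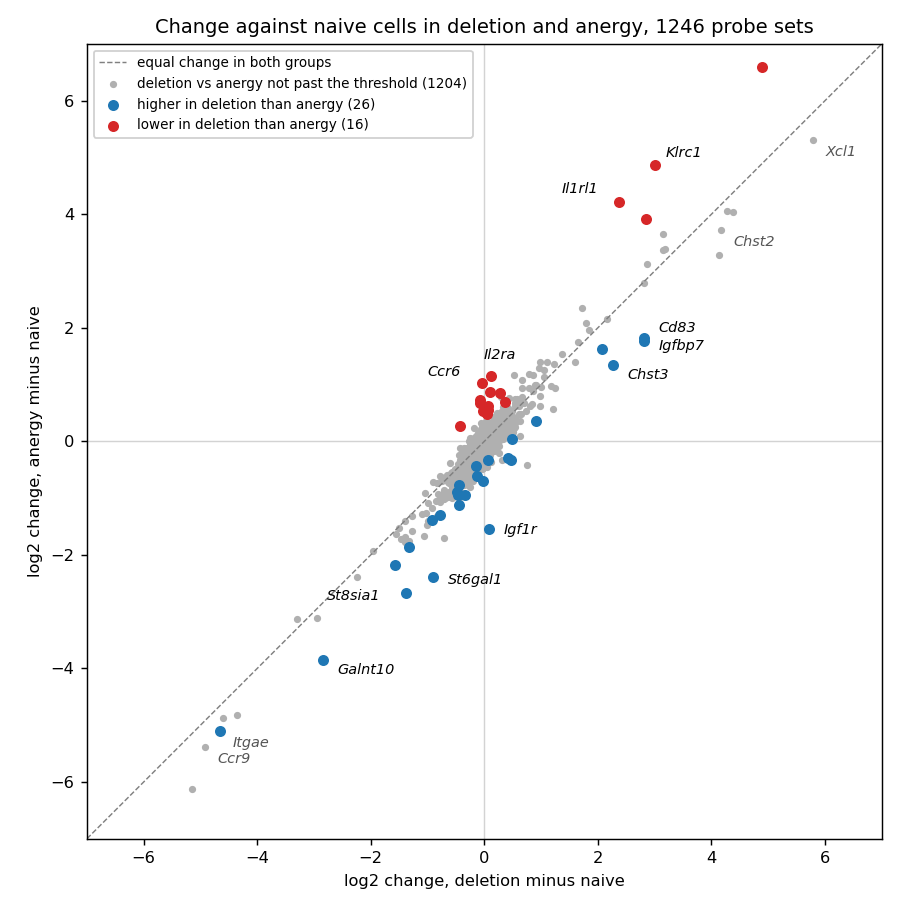
Log2 change against naive in deletion (horizontal axis) and in anergy (vertical axis) of 1246 probe sets, with 1 point per probe set, blue where deletion was higher than anergy (26) and red where it was lower (16). Points lie along the dashed line of equal change (r = 0.950), with Klrc1 and Il1rl1 above it and St6gal1, St8sia1, Galnt10 and Igf1r below it.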

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

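The tests of other splits of the arrays and of naive cells left among the deletion cells were chosen only after the results were seen. In 9 results the means of deletion and anergy lay on opposite sides of the naive mean and the difference between them passed, and these are given here for a closer look. Ccr6 was lower in deletion than in anergy, at -1.07 on the log2 scale (adjusted p = 0.000368), as were Prdm1 at -0.80 (0.00514), Cxcr4 at -0.74 (0.0191) and Il21 at -0.56 (0.00514). Each of these 4 passed against naive in anergy and not in deletion, where the changes were -0.05, -0.08, -0.07 and -0.03. Gm2a was 0.40 higher in deletion (0.0226) and Igf1r 1.62 higher (0.00637), and again only anergy passed against naive, at -0.33 and -1.54. Il12rb2, among the dimmest 33.3% of probe sets, was lower in deletion at -0.69 (0.000567), with -0.42 against naive in deletion and 0.27 in anergy, both past the threshold. Pecam1 was 0.72 higher (0.00234), with 0.43 and -0.30, also both past it, although the fall in anergy passed in only 7 of 17 settings. The unnamed probe set uc007lzi.1_psr1_s_at was 0.79 higher (0.00608), with 0.47 past the threshold in deletion and -0.32 not past it in anergy.

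The number of probe sets past the threshold was set against every other way to split the same 6 arrays into 3 and 3. Of the 10 splits, 1 gave as many as the real one in each comparison, namely the real one itself: 42 for deletion against anergy, 237 for deletion against naive and 334 for anergy against naive, with 0 as the highest other count in all 3. With 10 splits no share can come under 0.05, so these counts cannot tell the grouping from chance.

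For 27 of the 42 probe sets that differed between deletion and anergy, the deletion mean lay between naive and anergy, which naive cells left among the deletion cells could produce. The share of naive cells that each probe set would need was computed, and Itgae and Ccr9, which fell 25.3-fold and 30.2-fold in deletion, allowed 1.58% at most; 26 of the 27 (96.3%, with Itgae itself among the 27) needed more in each deletion array, with a median of 54.7%, 42.4% for St6gal1 and 74.6% for Klrc1. This argues against left-over naive cells as the whole cause, if the stimulated cells of both groups were alike. Anergy replicate 3 and a narrower scale of the deletion arrays were tested on other probe sets, those changed the same way against naive in both groups. The share of these farther from naive in anergy, 73.8% of 210, was 72.9% of 236 without that array and 70.2% of 242 after quantile normalization. Neither is thus likely as the whole cause of that wider pattern. For the 27 this was not tested, and of the 42 calls 29 held without anergy replicate 3 and 37 after quantile normalization. The SDs of the values of single arrays were 2.397, 2.425 and 2.398 in deletion and 2.409, 2.405 and 2.292 in anergy. These ranges overlapped and gave no sign of a narrower scale in deletion than in anergy. The weaker antigen signal that the design names for deletion stays open as a hypothesis, since no sample separates it from the other differences between these treatments.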

How the results depend on the processing

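The alternatives in this part were all listed before the data were examined, and none of them was chosen after its result was seen. The choice to give the blocked value beside results of deletion against anergy was made after the calls of the blocked fit had been seen. No called gene or list changed direction under any alternative. For deletion against anergy the 26 higher probe sets became 13 with median centring, 8 with only the 2 groups, 44 with array weights, 5 at 2-fold or more and 5 with no moderation, and leaving out 1 array gave 8 (deletion replicate 2) to 30 (anergy replicate 1). The 16 lower became 38 with quantile normalization, 31 with array weights, 6 at 2-fold or more, 9 with no moderation and 6 when the glycan-processing lists alone were tested, and 12 to 19 when 1 array was left out. Of the 42 calls, 37 held with quantile normalization, 26 with median centring, 20 with only the 2 groups and 42 with array weights. The 2-fold limit calls fewer probe sets by construction. The glycan-processing lists alone cover 253 probe sets, so their counts cannot be set against those over all 1246. Among these 253, 20 were higher and 6 lower when tested alone, against 11 and 2 in the main fit. For the other alternatives the cause was not tested.

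For deletion against naive, 32 rose and 27 fell by 2-fold or more, and for anergy against naive 38 and 42. Among the 253 glycan-processing probe sets tested alone, 28 rose and 43 fell in deletion, and 35 and 61 in anergy. The main fit gave 25 and 41, and 34 and 59, for these probe sets. All other counts of these 2 comparisons stayed within 1.5 times the main ones, and leaving out 1 array gave 78 to 114 and 104 to 153 for deletion, and 110 to 150 and 162 to 199 for anergy. The correlation of both changes ranged from 0.938 to 0.955. Named genes that passed kept their call in every setting run for them for 14 of 34 in deletion against anergy, 77 of 89 in deletion against naive and 92 of 96 in anergy against naive. Of the list calls 0 of 1, 0 of 2 and 0 of 4 did so. No moderation and the 2-fold limit were not among the settings run for single genes or lists.

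With a replicate block the counts were 33 and 22, 114 and 144, and 138 and 208. In deletion against anergy the block changed the calls given in the report and no other reported call. Naive arrays and arrays of the same number in deletion and anergy had deviations correlated at -0.14 and -0.15 for replicate 1, 0.12 and 0.27 for replicate 2 and -0.14 and 0.17 for replicate 3. These values were mixed in sign and do not settle whether the numbers pair the naive arrays with the others. For 6 of 9 arrays the best match outside the group had the same number, a hint from the data and not from the design. Signal over background was not used here, so what dim probe sets can show is limited by the lowest values, near 1.67.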

Other observations

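The test for natural killer cells was chosen only after the result was seen, and the tests of a compressed scale and of RNA of other cell types were written before their results. In the Notch list 5 of 14 genes fell and 0 rose in each stimulated group, although after median centring 2 fell in deletion and 5 in anergy: Notch1 (-0.38 in deletion and -0.78 in anergy), Notch2 (-0.60 and -0.91), the ligand Jag2 (-0.40 and -0.65), and Lfng and Mfng, which extend O-fucose on Notch. The list was not called (adjusted p = 0.131 and 0.161), and between deletion and anergy 0 of 14 passed, with a median of -0.01, a mean of 0.08 and direction up. In the TGF-beta list 5 of 18 fell and 0 rose in deletion, and 7 fell and 1 rose in anergy (3 rose after quantile normalization and 0 without anergy replicate 3), with these among the falls: Tgfbr1 (-0.92 and -1.17), Tgfbr2 (-1.02 and -1.47) and Tgfbr3 (-3.29 and -3.14). Both interferon-gamma receptor chains fell, Ifngr1 by 0.63 and 0.71 and Ifngr2 by 1.96 and 1.93 on the log2 scale, while Ifng rose; the interferon and TNF list had a median of -0.15, a mean of 0.26 and direction down in deletion, and -0.425, 0.08 and down in anergy, and was not called. Among 63 interleukins and receptors 10 rose and 8 fell in deletion, and 11 and 9 in anergy, with both chains of the interleukin-18 receptor up, Il18r1 (1.66 and 1.75) and Il18rap (1.59 and 1.40), and with Il18 itself up (1.11 and 1.39).

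Some genes rose in both groups and belonged to no list in use here. The rule named Cks1b (3.14 in deletion and 3.38 in anergy) and Cks2 (3.18 and 3.38), which bind cell cycle kinases, and Angptl2 (2.81 and 2.79). The chromatin protein Hmgn2 (1.36 and 1.55) and Psen2, a catalytic subunit of gamma-secretase (2.07 and 1.62), rose too and were chosen after their values were seen. Igf1r, named by the rule, stood at 0.08 in deletion, not past the threshold, and fell by 1.54 in anergy. The largest change of all was in the unnamed probe set uc009ego.1_psr1_at, with means of 2.73 in naive, 7.63 in deletion and 9.33 in anergy.

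Anergy replicate 3 stood apart from its group, with an array weight of 0.196, and read lower by a median of 0.255 among the brightest probe sets and higher by 0.05 among the dimmest. A compressed scale of values could cause this, and quantile normalization took its residual SD from 0.166 to 0.142, against at most 0.128 in the other arrays, so it may account for part and not for the whole. RNA of other cell types was tested with 50 markers, whose median deviation on this array lay at percentile 60.9 of 10000 level-matched random lists, which leaves this open. The design gives no difference between this sample and the other anergy samples.

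Klrc1 rose 8.06-fold in deletion and 29.4-fold in anergy, and natural killer cells among the stimulated cells could bring this about, since they express it, although the labels give the cells as purified CD8 T cells. None of the 4 measured natural killer markers passed, and in anergy, where Klrc1 rose most, the upper 95% limits of their log2 changes were 0.09 for Klra8, 0.24 for Klra4, 0.15 for Klra3 and 0.37 for Klra9. In deletion they were 0.14, 0.16 and 0.16 for the first 3 and 1.00 for Klra9, which just reached the bound of 1 set for the test, so this explanation stays open there. Klra3 and Klra4 lay near the lowest values, and Klra8 also lay in the dimmest 33.3% of probe sets, so the limits of these markers show little. Klrd1, whose product pairs with that of Klrc1, fell by 1.04 and 0.92 on the log2 scale. Of 17 lectin receptors of the natural killer type 4 rose and 2 fell in anergy, with Klrk1 (0.79) and Klrc3 (0.63) among the rises. Expression by the stimulated CD8 T cells themselves stays open as a hypothesis, which these arrays of bulk RNA cannot separate from a few natural killer cells.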
